A study of Drosophila melanogaster with 12 samples.

How the data were processed

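RNA was measured in whole embryos of an EGFP-vasa strain of Drosophila melanogaster on 12 two-colour Agilent arrays, 1 for each collection window. Per the labels, total RNA was purified on RNeasy columns and amplified and labelled with Agilent's fluorescent linear amplification kit for low RNA input. Cy3 held the embryos of the window and Cy5 a pool of embryos of 0 to 24 h that served as the common reference on every array. No dye was swapped and no window was repeated.

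Per the file headers, the spot intensity values are the scanner's mean pixel brightness per spot and the median of its local background, as written by Agilent Feature Extraction A.7.1.1 with no background subtracted and no normalization. The same deposited files hold a log10 ratio of Cy5 to Cy3, which per the file headers was made after background subtraction and LOWESS dye normalization by the same software. The deposited value table holds log2 ratios of Cy3 to Cy5. They equal the log10 ratio with its sign turned and its base changed, within 9.6e-08 on every array, so their scale, their direction and the absence of further centring were read from the values. The medians of its columns from window 0 to window 11 were 0.093, 0.071, 0.081, 0.027, 0.014, 0.022, 0.0074, 0.0013, -0.0029, -0.052, -0.043 and -0.052. No other per-sample column of the deposited files entered a comparison except the software's marks for outlier spots and for spots well above background.

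The arrays held 22575 spots, of which 651 were controls and 21924 were probes for genes. Probe names carry 13693 CG numbers. Of these, 11717 matched a locus tag and 1129 a synonym in a RefSeq table of the Release 6 assembly, and 847 matched neither and kept their CG number. The table was used for gene symbols and for the number of transcripts per gene. The files do not name the genome build of the array design, so no coordinates are given.

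Mean signals were corrected with the local background by normexp with an offset of 50. Ratios were then normalised within each array by loess, in which control and outlier spots had no weight, and outlier spots were set to missing. Both steps used limma 3.58.1 in R 4.3.3. A probe was kept if the software called it well above background in Cy3 on at least 3 of 12 arrays, which 21231 probes were, and 304 probes were never so. Each gene was represented by its brightest probe, the one with the highest mean log2 intensity over both channels and all arrays. This left 12855 of 13190 genes, 6640 of which had more than 1 kept probe. The other probes of the named genes were fitted by the same model, a comparison chosen after seeing the data. Tables were handled with dplyr 1.1.4 and jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

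The windows were grouped into 4 periods of 3 successive windows. A single limma model of the 4 period means (lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom) gave the 4 comparisons, namely period 2 against 1, 3 against 2, 4 against 3 and 4 against 1. The stage trend was limma's F-test of a natural spline with 4 degrees of freedom in window number, which leaves 7 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes tested, and genes passed at an adjusted p under 0.05. Standard errors are the moderated ones of limma. Since windows of a period are successive ages, the spread they give (a median of 0.232 on the log2 scale) holds development as well as noise. The order of the arrays was tested by correlating the first principal component with window number, with 1e+05 permutations.

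A set of 30 gene lists with 767 entries, of which 739 were on the array, was tested with camera, which compares a list with all other genes. The correlation among the genes of a list was preset to 0.01, and the test was repeated with that correlation estimated. Its p-values were adjusted over the lists within each comparison. Genes named in the text follow a rule. It takes, for each comparison, the 8 largest rises and the 8 largest falls in log2 among genes that passed, whose arrays did not overlap between the periods and that had a symbol other than an identifier. It also takes up to 4 members of each list that passed, with the largest change in the direction of the list's median, and 30 landmark genes at every window. The windows' grouping, the tests, the lists, the rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

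The test was tried on simulated data of 12664 genes in which 200 were given a change. The noise was normal and independent between genes and arrays, with no drift within a period and no day effect. The shares therefore describe the test on such data, and not on successive ages. At a log2 change of 1 the recovered share was 65% for period 2 against 1, 66% for 3 against 2, 62% for 4 against 3 and 64% for 4 against 1. At a log2 change of 2 these shares were 89%, 87%, 87% and 88%. False calls made up 7.78%, 6.71%, 3.25% and 4.4% of the calls. For the stage trend, where the change given was a straight line over the windows, the recovered shares were 40% and 66%, with 4.5% false calls.

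The file headers give the day on which the software extracted each image, and not the days of RNA preparation, labelling or hybridisation. These image extraction days put windows 0 and 1, windows 2 to 5, windows 6 to 8 and windows 9 to 11 together. As a fixed block the day could be fitted for the stage trend and for period 2 against 1, and in the other comparisons it was confounded with the periods. As a random block (a correlation of 0.237 within days by duplicateCorrelation) it was fitted for all 4 comparisons, an alternative chosen after seeing the data.

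The other alternatives were no background subtraction, median centring in place of loess, the software's own ratios, the deposited value table, Cy3 alone after quantile normalization, no filter on dim probes, a filter on the Cy5 reference on all 12 arrays, the mean of all probes of a gene, an eBayes prior with trend and robust fitting, and leaving out each array in turn. The stage trend was also fitted with 3 degrees of freedom, as a straight line and over the midpoint of each window in hours. Spots marked as outliers, control spots and probes that were not well above background on enough arrays were left out. No test compared single windows, because each had 1 array.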

Results

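Transcript levels were measured in whole Drosophila melanogaster embryos of an EGFP-vasa strain, in which a vasa transgene carries green fluorescent protein, at 12 successive collection windows that together span embryogenesis. Embryos developed at 25 degrees C, and total RNA of each window was labelled with Cy3 and hybridised to its own array. The other channel of every array held a Cy5-labelled common reference, a pool of embryos of 0 to 24 h after egg laying. A ratio is therefore the level in 1 window relative to the average embryo, and a transcript near a log2 ratio of 0 may be high or low in absolute terms. The windows are numbered here from 0 to 11 in order. Window 0 ended at 1 h 20 min, and windows 1 to 4 followed at intervals of 1 h and ended at 5 h 20 min. Windows 5 to 8 ended at 7 h 20 min, 9 h 20 min, 11 h 20 min and 13 h 20 min. Windows 9 to 11 ended at 16 h 20 min, 19 h 20 min and 24 h 0 min. Each window had 1 array and no replicate. The tests that follow compare 4 periods of the time course, which hold 3 successive windows each (windows 0 to 2, 3 to 5, 6 to 8 and 9 to 11), or fit a curve through all 12 windows, so their p-values set a change against the spread between neighbouring ages and not against the spread between biological replicates.

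The median spot intensity of the Cy3 channel lay between 140 and 240 units, and that of the Cy5 channel between 173 and 320 units. Between 89.02% and 96.7% of probes were well above background in Cy3, and between 95.7% and 98.0% in Cy5. The array of 16h20m - 19h20m stood apart, with the lowest Cy3 median, the highest Cy5 median and a Cy5 background of 87 units, against 48 to 55 units on the other arrays. The number of arrays limits the precision of every value.

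The arrays fell in the order of their labels. The first principal component of the log2 ratios held 54.7% of the variance and the second 23.3%. The first component followed window number with a Spearman rho of 1 over 12 arrays (permutation p = 1e-05, the smallest that the permutations can give; the Benjamini-Hochberg value was the same) and a Pearson r of 0.970 (permutation p = 1e-05). Without the 2 arrays farthest from the median window r was 0.969. The Cy5 channel varied less than Cy3. Its values correlated across genes with a median r of 0.995 between arrays (lowest 0.949), against 0.847 for Cy3 (lowest 0.571). The Cy3 values spread more than the Cy5 values in 97.7% of genes, with median standard deviations of 0.45 and 0.14 on the log2 scale. The reference was not free of differences between periods. Fitted alone by limma, Cy5 gave 0, 0, 22 and 208 calls in the 4 comparisons that follow, and 1213, 443, 2162 and 4437 genes had an unadjusted p under 0.05. Of 66 pairs of arrays, 11 had ratios that correlated below -0.3 across genes, the lowest at r = -0.555. The first windows opposed the middle ones, as window 1 did windows 6 to 8 (r = -0.436, -0.53 and -0.442), while windows 0 and 1 correlated with windows 9 to 11 between -0.215 and 0.00048. The labels state which dye held which RNA, and their direction was kept.

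The maternal transcripts were highest in the first windows and left in steps. The log2 ratio of osk (CG10901), which organises the germ plasm, was 2.35 in window 0, 1.90 in window 1, -0.60 in window 2 and -2.12 in window 3. That of nanos (CG5637), a posterior determinant, went from 2.91 to 2.06 and then to -1.18 in window 2. Hsp83 (CG1242), a chaperone transcript that is cleared from the bulk of the early embryo, went from 2.31 to 1.5 and then to -2.37. The ratio of bcd (CG1034), the anterior determinant, was 0.90 and 1.04 in windows 0 and 1 and 0.22 in window 2, and that of smg (CG5263), a regulator of maternal transcript decay, was 0.98, 1.12 and 0.24. The vas probe (CG3506) read 2.35 in window 0 and -0.47 in window 2, and in this strain its signal cannot be told from that of the transgene. CycB (CG3510), a mitotic cyclin, stayed near 1.2 in windows 0 and 1, lay at -1.58 in window 10 and reached -4.09 in window 11.

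Zygotic landmarks followed in turn. The ratio of nullo (CG14426), which acts in cellularisation, was -0.76, 1.48, 1.14 and -1.14 in windows 0 to 3. The pair-rule genes eve (CG2328) and ftz (CG2047) both peaked in window 2, at 1.52 and 1.69, from -1.66 and -1.96 in window 0, and were back at -1.11 and -1.01 in window 4. The gap gene Kr (CG3340) peaked in window 2 at 0.76, and the mesoderm determinants twi (CG2956) and sna (CG3956) peaked in window 3 at 1.38 and 0.26. The segment polarity gene en (CG9015) went from -4.86 in window 0 to 0.61 in window 3 and peaked in window 5 at 0.95, and wg (CG4889) peaked in window 3 at 0.36. The brightest probes of Ubx (CG10388) and Abd-B (CG11648), homeotic genes of the trunk and abdomen, peaked in window 6 at 0.51 and 0.72. In the nervous system, the brightest probes of the neuroblast genes dpn (CG8704) and pros (CG17228) peaked in window 5 at 0.61 and 0.42, and the neuronal RNA-binding gene elav (CG4262) rose from -5.12 to its peak of 0.98 in window 7. Mef2 (CG1429), a muscle transcription factor, peaked in window 6 at 1.08 by its brightest probe, and 2 of its 7 probes peaked in windows 10 and 11 at 0.43 and 0.45.

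By their brightest probes, the late landmarks Act57B, Mlc2, Mhc and Col4a1 covered the widest ranges of the landmarks. The brightest probe of Act57B (CG10067), a larval muscle actin, rose from -5.40 in window 0 to 4.09 in window 10, Mlc2 (CG2184), a myosin light chain, from -3.91 to 5.03, and Mhc (CG17927), the muscle myosin heavy chain, from -2.94 to 3.91 in window 9. Col4a1 (CG4145), a basement membrane collagen, rose from -2.67 to 3.89 in window 10. kkv (CG2666), a chitin synthase, peaked in window 9 at 2.69. The digestive protease gene Jon99Ci (CG31039) read 0.30 in window 9, 1.75 in window 10 and 5.31 in window 11. Lsp2 (CG6806), a larval serum protein gene, stayed between -0.05 and 0.24. The brightest probe stands for a gene throughout, and in several landmarks another probe had a different course or range. The other probes are dimmer by this rule, and the offset added in background correction shrinks the ranges of dim spots. The other Act57B probe went from -1.18 in window 0 to 2.18 in window 11. That of Abd-B peaked in window 3 at 0.33 and ended at -0.77, and 1 of 4 pros probes peaked in window 11 at 1.52. The other Mhc probe peaked in window 11 at 4.94 and the other wg probe in window 5 at 0.099, and the other probes of Ubx and vas ranged over only 0.163 and 0.226. Further differences were found for bnk (CG1480), a cellularisation gene, and repo (CG31240), a glial gene. The brightest bnk probe went from -0.59 to 1.82 in window 11 while the dimmer probe read -1.71, 0.95, 1.80 and -2.80 in windows 0 to 3. The brightest repo probe read 0.17 in window 0 and -0.17 in window 7, and the dimmer one -1.42 and 0.94.

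**Figure D1:**
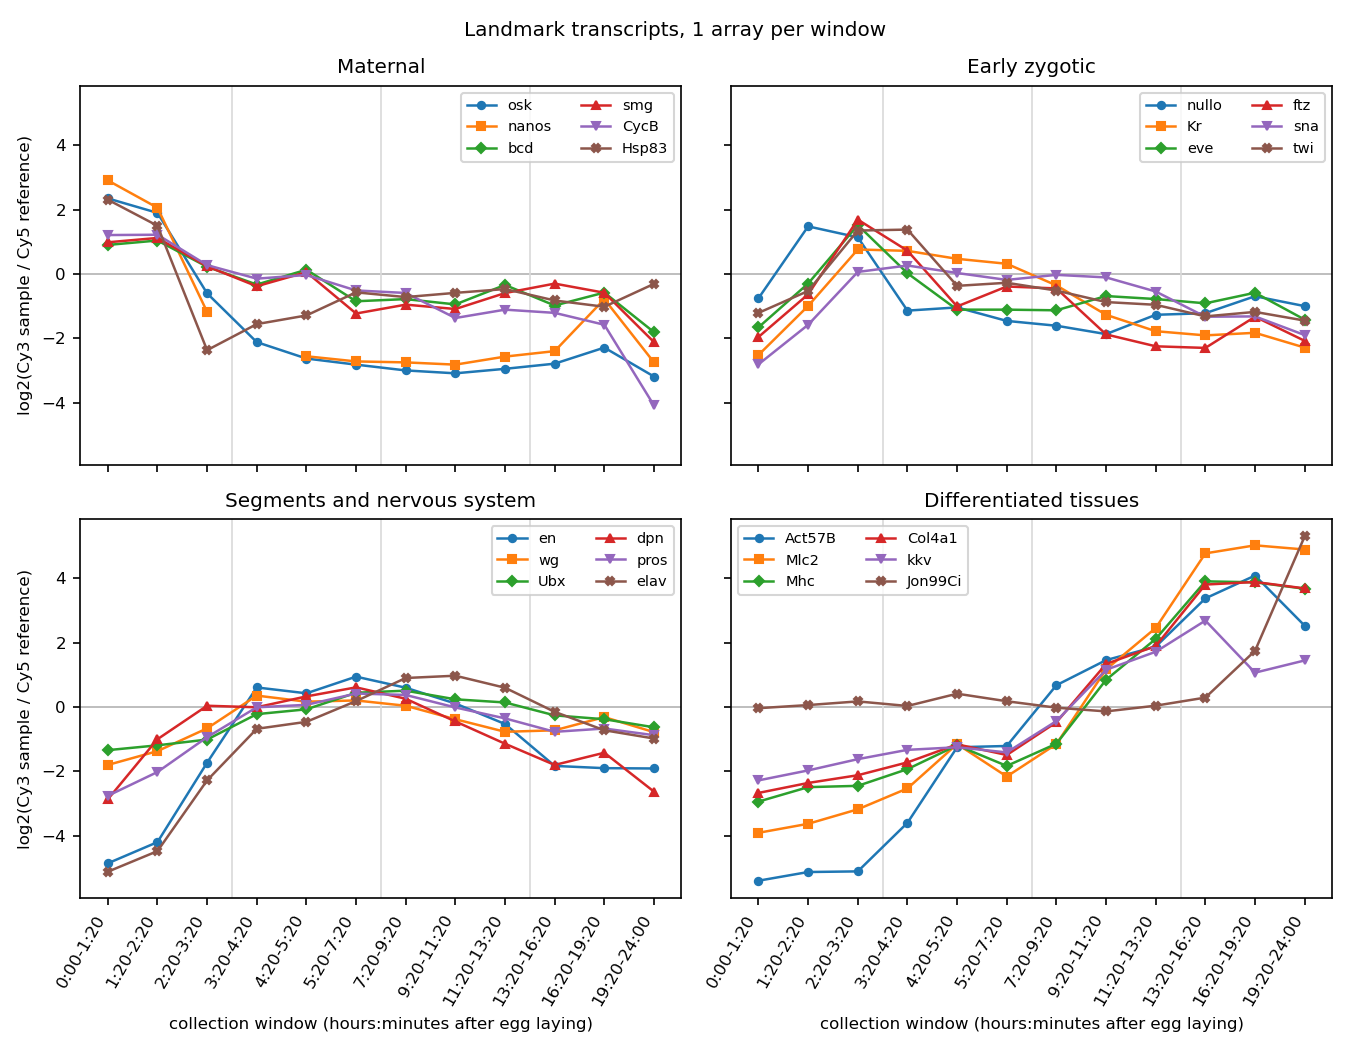
Log2 ratio of Cy3 sample to Cy5 reference (y axis) against window number (x axis) for landmark genes in 4 panels, maternal, early zygotic, segment and nervous system, and differentiated tissue genes, with 1 array per point and no error bar because no window has a replicate. The maternal genes osk and nanos start at 2.35 and 2.91, eve and ftz peak in window 2, and Mlc2 reaches 5.03 in window 10; the gap in nanos is a spot that the scanner software marked as an outlier.

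The size of the change from one window to the next was uneven. Between windows 1 and 2 the root mean square log2 step was 0.589, and 1099 genes differed by more than 2-fold, of which 786 were lower in the later window. Between windows 2 and 3 the step was 0.496, and 652 genes were more than 2-fold higher and 161 lower. The steps between windows 3 and 6 (0.231 to 0.256) and between windows 7 and 8 (0.238) were the smallest. The steps from window 8 to window 9 (0.634) and from window 10 to window 11 (0.655) were the largest, with 881 genes over 2-fold higher and 121 lower in the first, and 780 higher and 462 lower in the second. The later windows are also longer, at 3 h or more against 1 h. The same steps in the Cy5 reference lay between 0.123 and 0.204, except for 0.415 and 0.402 before and after the array of 16h20m - 19h20m. Since each step compares single arrays, none was tested.

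**Figure D2:**
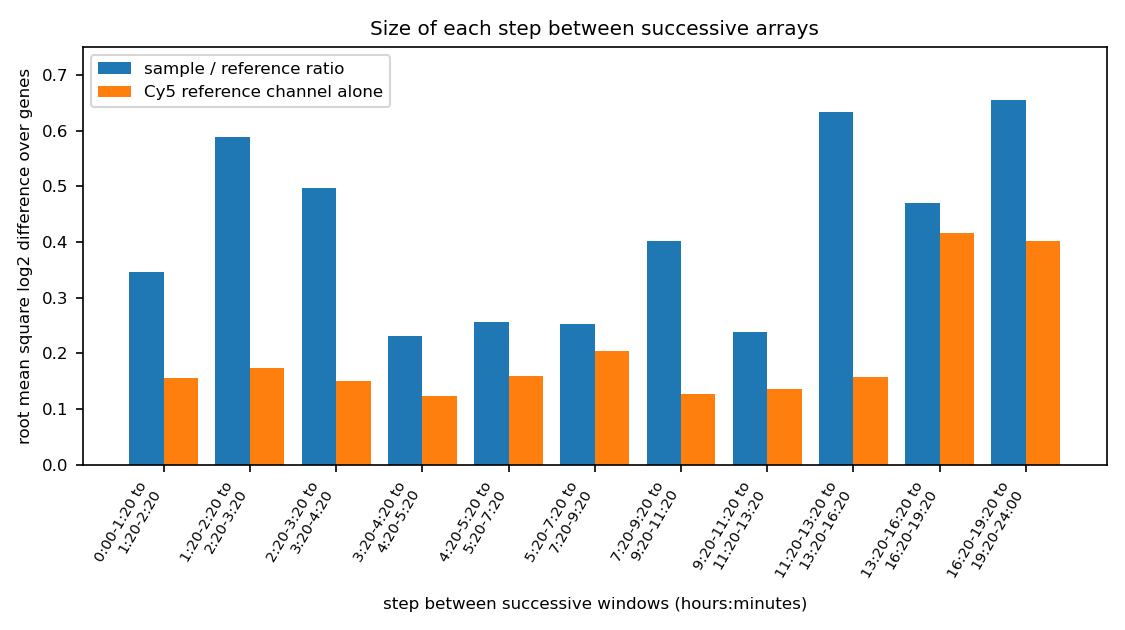
Root mean square of the log2 change over all tested genes between successive windows (y axis, log2 units) for the sample to reference ratio and for the Cy5 reference alone (bars, 1 value per pair of arrays). The ratio steps peak between windows 1 and 2 at 0.589, between windows 8 and 9 at 0.634 and between windows 10 and 11 at 0.655, and the reference steps exceed 0.204 only on both sides of window 10.

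The stage trend, a smooth course across the 12 windows, was found for most genes. Of 12855 genes tested, 9736 (75.7%) passed the spline test at an adjusted p under 0.05, and the measured ratios of 7289 of these ranged over more than 2-fold and of 3564 over more than 4-fold. The median range of the genes that passed was 1.59 on the log2 scale. Among those with a range above 2-fold, 2176 (29.9%) had their highest ratio in window 11, 1159 (15.9%) in window 0, 771 (10.6%) in window 9 and 707 (9.7%) in window 2, and only 88 (1.21%) in window 4. The landmarks Col4a1 (adjusted p = 2.6e-06), Mhc (3.6e-06), pros (4.1e-06), Kr (1.7e-05) and osk (2.1e-05) passed by a wide margin. Of other early landmarks, ftz (adjusted p = 0.0175) and eve (0.0442) passed narrowly, and nullo (0.0503) did not pass. Lsp2 did not pass (0.321). The scanner software had read the array images on 4 days that follow the windows and change between windows 1 and 2, 5 and 6, and 8 and 9 (the days of RNA preparation and hybridisation are not given). With this image extraction day as a block, which takes out most of the course itself, 1749 genes passed.

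Folds in the comparisons that follow are those of the brightest probe. Of 268 named results that passed in genes with more than 1 probe, another probe's change differed by more than 2-fold in 138, by more than 4-fold in 61 and had the opposite sign in 33. The other probes are dimmer by the rule that chose the brightest one. The offset added in background correction shrinks the changes of dim spots, so a smaller change in another probe need not be a different course. The examples of such probes given here were chosen after their values were seen.

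The first comparison, period 2 against period 1, set the windows between 3h20m and 7h20m against those up to 3h20m, which span the passage from maternal to zygotic transcripts. Among the largest rises were Obp99a (CG18111), an odorant-binding protein gene (27.7-fold, log2 4.79 ± 0.56 SE, n = 3 arrays in each period, adjusted p = 0.0017), smal (CG31640), which encodes a discoidin domain receptor (24.8-fold), and rib (CG7230), a nuclear factor of tracheal and salivary gland morphogenesis (22.3-fold). LanA (CG10236), a laminin chain of basement membranes, rose 20.4-fold (log2 4.35 ± 0.46), en 19.1-fold (4.26 ± 0.66) and Toll-6 (CG7250), a Toll family receptor, 18.6-fold. The steepest falls were those of bru1 (CG31762), which represses osk translation in the ovary (21.1-fold lower, log2 -4.40 ± 0.97, adjusted p = 0.0146), and Eno (CG17654), the glycolytic enolase (20-fold lower). yl (CG1372), the yolk protein receptor of the oocyte, was 18.7-fold lower, and Jabba (CG15092), which holds histones on lipid droplets, 14.1-fold lower. osk fell 13.4-fold (log2 -3.74 ± 0.63). The most different other probe gave a log2 change of -0.012 for smal, -0.26 for bru1, 1.34 (2.54-fold) for en and 1.73 (3.31-fold) for rib. Obp99a, smal, rib, LanA, en, Toll-6 and osk kept their call under every alternative tried. The calls of bru1, Eno, yl and Jabba were lost with image extraction day as a block and without the array of 1h20m - 2h20m or 5h20m - 7h20m. In this comparison the block sets only window 2 against windows 3 to 5, so a fall before window 2 no longer counts. A call lost with the block therefore does not tell day from age.

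By lists fixed before the data were examined, neuroblast and neurogenic genes had the most rises. Of 28 members, 23 rose and 5 did not pass (26 rose when adjusted over the list alone), with a median log2 change of 1.97. Among them were E(spl)mbeta-HLH (CG14548; 11.2-fold) and E(spl)mgamma-HLH (CG8333; 10.8-fold), which are Notch targets. The list differed from other genes by camera (adjusted p = 1.5e-14), but not when the correlation among its genes was estimated (adjusted p = 0.197 with an estimated correlation). Of 19 pair-rule and segment polarity genes 11 rose (11 adjusted over the list alone), with en foremost. Of 9 Hox genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), led by abd-A (CG10325; 12.3-fold, and 1.25-fold by its other probe) and Abd-B (5.85-fold, and 1.68-fold by its other probe). Of 22 mesoderm and myoblast genes 15 rose and 1 fell (19 and 1 adjusted over the list alone), with bap (CG7902), a gene of the visceral mesoderm, 9.2-fold higher (1.42-fold by its other probe). Tracheal genes gave 11 rises and 1 fall among 13 (11 and 1 adjusted over the list alone), including rib and sty (CG1921), an FGF pathway inhibitor (8.04-fold). Endoderm factors gave 6 rises and 1 fall among 9 (6 and 1 adjusted over the list alone), including peb (CG12212; 10.5-fold). Glia genes gave 7 rises among 13 (10 adjusted over the list alone), including nrv2 (CG9261), a sodium pump subunit (16.4-fold). Hemocyte and basement membrane genes gave 9 rises among 25 (10 adjusted over the list alone), including LanA and LanB1 (CG7123; 13.1-fold). These last 7 lists passed camera (adjusted p between 1.2e-09 and 3.3e-04). None of the 7 did so when the correlation was estimated (adjusted p = 0.197 with an estimated correlation for the lowest and 0.359 for the highest).

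Falls outnumbered rises by the most in 3 lists. Of 29 maternal patterning and egg activation genes 18 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -1.41. Among them were BicC (CG4824; 12.4-fold lower) and cup (CG11181; 4.75-fold lower), which bind maternal mRNA and whose calls were lost with image extraction day as a block. Of 17 germ plasm and posterior mRNAs 7 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.14. Of 31 proteasome subunits 9 fell and none rose (12 fell adjusted over the list alone), with a median of -0.59, led by Prosalpha1 (CG18495; 3.43-fold lower, log2 -1.78 ± 0.24). Camera gave adjusted p = 1.3e-12, 3.5e-05 and 3.2e-07 for these 3 lists, and each call was lost when the correlation was estimated (adjusted p = 0.197, 0.338 and 0.283 with an estimated correlation). The 31 first zygotic genes split, with 5 rises, 4 falls and 22 that did not pass (6 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.713). Ance (CG8827), a peptidase gene, rose 17.3-fold, while nullo fell 3.57-fold, a call that was lost with image extraction day as a block. Of 31 neuron differentiation genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.237), with elav 12.5-fold higher. Of 27 muscle structural genes 5 rose (5 adjusted over the list alone). The muscle list passed camera (adjusted p = 0.0186) but not with median centring, nor when the correlation was estimated (adjusted p = 0.63 with an estimated correlation).

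Over all 12855 genes, 1214 were higher and 815 lower at an adjusted p under 0.05 (2029 in all, 15.8%), of which 693 and 366 changed more than 2-fold. In 40.3% of genes the 3 arrays of one period did not overlap the 3 of the other. Chance gives 10% for exchangeable arrays, those whose order does not matter, which successive ages are not. A drift with age or day raises the share, here and in the later comparisons, so 10% is no benchmark for it. With median centring in place of loess 35.6% of the calls were higher, against 59.8%. With image extraction day as a block, which compares window 2 with windows 3 to 5 of the same day, 521 genes passed, and with the day as a random block 1266. The count was 947 without the array of 5h20m - 7h20m, 964 without 1h20m - 2h20m, 1312 without 4h20m - 5h20m and 3470 without 2h20m - 3h20m.

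The second comparison, period 3 against period 2, covered the windows from 7h20m to 13h20m against those from 3h20m to 7h20m, when the germ band shortens and organs form. Fewer genes passed, although the periods did not overlap in about as many genes as in the first comparison. Rises included Neurochondrin (CG2330; 14.3-fold, log2 3.84 ± 0.78, adjusted p = 0.0432), verm (CG8756), a chitin deacetylase of the tracheal lumen (11.9-fold, 3.58 ± 0.68), and Act57B (10.3-fold, 3.36 ± 0.64, and 2.08-fold by its other probe). Tig (CG11527), a matrix ligand of integrins, rose 7.64-fold, and fne (CG4396), a neuronal RNA-binding gene, 6.83-fold (adjusted p = 0.0271). Falls included wntD (CG8458), an inhibitor of Dorsal signalling (8.07-fold lower, log2 -3.01 ± 0.61), and genes of DNA replication and histone supply. These were Slbp (CG11886), the stem-loop binding protein of histone mRNA (3.96-fold lower), PolE1 (CG6768), a DNA polymerase subunit (3.14-fold lower), and the histone genes His4:CG31611 (3.12-fold lower) and His2B:CG17949 (2.93-fold lower). Histone genes are repeated, and near-identical copies share a probe's signal.

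Of 52 cell cycle and DNA replication genes 2 fell over all genes tested and 29 when adjusted over the list alone, with a median of -1.02. The 27 muscle structural genes had a median of 1.05 and 3 rises (15 adjusted over the list alone), namely Act57B, Mlc1 (CG5596; 6.13-fold, a call lost with the mean of all probes) and sls (CG1915; 1.93-fold). Of 25 hemocyte and basement membrane genes 5 rose (12 adjusted over the list alone), with a median of 0.79, including both collagen IV chains vkg (CG16858; 5.36-fold) and Col4a1 (5.19-fold) and SPARC (CG6378; 4.9-fold). Camera gave these 3 lists adjusted p = 9.2e-18, 8.9e-09 and 2.6e-04, and none passed when the correlation was estimated (adjusted p = 0.597 with an estimated correlation for each). Mesoderm and myoblast genes gave 4 rises and 1 fall among 22 (6 and 2 adjusted over the list alone), and glia genes 2 rises among 13 (2 adjusted over the list alone). Hand (CG18144), a heart gene, was 3.03-fold higher and well above background on 2 of the 3 earlier arrays, kirre (CG3653), which acts in myoblast fusion, 2.3-fold higher, and the glial wrapper (CG10382) 2.73-fold higher. Of 28 neuroblast and neurogenic genes 1, the proneural ato (CG7508; 2.75-fold lower), fell (6 adjusted over the list alone), with a median of -0.46. The mesoderm, glia and neuroblast lists passed camera (adjusted p = 0.0136, 0.0395 and 0.0022) but not when the correlation was estimated (adjusted p = 0.597, 0.597 and 0.744 with an estimated correlation), and the glia call was lost with the scanner software's ratios. Of 28 oxidative phosphorylation genes 1 rose (6 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 6.6e-06, but adjusted p = 0.597 with an estimated correlation). Fat body and hemolymph genes gave 3 rises among 13 (5 adjusted over the list alone), with apolpp (CG11064), the lipoprotein precursor, 5.07-fold higher (a call also lost with the mean of all probes), and did not pass camera (adjusted p = 0.0686).

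In all, 271 genes were higher and 41 lower (312 of 12855, 2.43%), and 178 and 22 of these changed more than 2-fold. An unadjusted p under 0.05 was reached by 2435 genes, and in 40.2% of genes the periods did not overlap (chance 10% for exchangeable arrays). The calls lay close to the threshold. None passed with image extraction day as a random block, or without the array of 1h20m - 2h20m, 3h20m - 4h20m, 4h20m - 5h20m, 9h20m - 11h20m or 11h20m - 13h20m, where limma gave between 1324 and 2197 genes an unadjusted p under 0.05. The count was 1258 without 7h20m - 9h20m, 653 without 2h20m - 3h20m, 483 without 19h20m - 24h00m, 170 without 5h20m - 7h20m, 76 without 0h0m - 1h20m and 69 without 16h20m - 19h20m. It was 152 without background subtraction, 495 with the scanner software's own ratios and 201 from the Cy3 channel alone, where 76.1% of the calls were higher against 86.9%. The images of periods 2 and 3 were read on different days, so the day and the age cannot be told apart here.

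The third comparison, period 4 against period 3, set the last windows, from 13h20m to 24h00m, against those from 7h20m to 13h20m and covered terminal differentiation. The largest rises were those of EAChm (CG13463; 44.2-fold, log2 5.46 ± 0.37, adjusted p = 2.1e-05), Vajk3 (CG16884), a cuticle protein gene (38-fold), and Cpr65Ax2 (CG18777; 31.4-fold) of the chitin-binding cuticle family. Mhcl (CG31045), a myosin-like heavy chain gene, rose 29-fold, Cpr65Av (CG32405), another cuticle gene, 26.9-fold, and Cbp53E (CG6702), a neuronal calcium-binding protein gene, 26.7-fold. Among the falls, nw (CG33006) was 16.6-fold lower (log2 -4.05 ± 0.45, adjusted p = 3.8e-04) and the engulfment receptor gene NimC4 (CG16876) 8.7-fold lower. nerfin-1 (CG13906), a zinc-finger gene of young neurons, was 7.29-fold lower (log2 -2.87 ± 0.48), and insb (CG6520), which acts in Notch repression, 6.83-fold lower. The most different other probe gave a log2 change of 1.48 (2.79-fold) for Vajk3, -0.10 for Mhcl, 2.55 (5.84-fold) for Cbp53E, -1.91 for nw and -0.31 for nerfin-1. All of these genes kept their call under every alternative tried, the mean of all probes included.

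Of 27 muscle structural genes 23 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 2.96. CG9297, a sarcoplasmic calcium-binding gene, rose 19.5-fold, Mlc2 16.9-fold, Prm (CG5939), paramyosin, 15.5-fold and bt (CG32019), the titin-like projectin, 15.2-fold. Their most different other probes rose less or did not pass, at 1.64-fold, 3.82-fold, 1.22-fold and 3.6-fold. Of 57 cuticle and chitin genes 34 rose and none fell (35 rose adjusted over the list alone), with a median of 1.10. Lcp65Ac (CG6956) rose 26.6-fold and Lcp65Ag1 (CG10530) 26.1-fold. On the array of 16h20m - 19h20m the Cy5 reference of the cuticle list lay a median of 0.46 log2 units above its level on the other arrays. That is the direction that lowers the ratio. The reference of the genes named here lay further above, by 2.85 for Lcp65Ag1, 2.56 for Lcp65Ac, 2.52 for Cpr65Ax2 and 2.04 for Cpr65Av. Their Cy3 signal was also raised, and their log2 ratios on this array were 5.66, 5.19, 5.40 and 5.25 in that order. The means of both neighbouring windows were lower, at 4.68, 4.78, 4.88 and 4.57. Of 28 oxidative phosphorylation genes 27 rose (28 adjusted over the list alone), with a median of 0.98, among them SdhC (CG6666), a subunit of succinate dehydrogenase, 2.32-fold higher, whose call was lost with median centring. Camera gave adjusted p = 3.7e-09 for muscle, 3.1e-09 for cuticle and 1.4e-12 for oxidative phosphorylation, and none passed when the correlation was estimated (adjusted p = 0.503, 0.278 and 0.503 with an estimated correlation). Neuron differentiation genes gave 21 rises and 1 fall among 31 (23 and 2 adjusted over the list alone), with a median of 0.66. They included nrv3 (CG8663), a neuronal sodium pump subunit (10.3-fold), Ddc (CG10697), which makes dopamine and serotonin and also serves the cuticle (5-fold), and Nrx-1 (CG7050), a synaptic adhesion gene (3.58-fold). Midgut digestive enzymes gave 15 rises among 33 (15 adjusted over the list alone), with a median of 1.70, including Mal-A3 (CG8695), a maltase (14.3-fold), and zetaTry (CG12387), a trypsin (7.49-fold). Their median ratio was 0.38, 0.99 and 3.62 in windows 9, 10 and 11. The neuron and midgut lists passed camera (adjusted p = 1.9e-07 and 1.2e-06) but not when the correlation was estimated (adjusted p = 0.503 and 0.588 with an estimated correlation). Hemocyte and basement membrane genes gave 8 rises and 1 fall among 25 (9 and 1 adjusted over the list alone; camera adjusted p = 0.198), with Glt (CG9280), glutactin, 14.4-fold and vkg 8.63-fold higher, and a list median of 0.19 that turned to -0.049 with median centring.

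Of 52 cell cycle and DNA replication genes 22 fell and none rose (27 fell adjusted over the list alone), with a median of -0.99. stg (CG1395), the Cdc25 phosphatase that triggers mitosis, was 6.42-fold lower (log2 -2.68 ± 0.54), a call lost with the day as a random block. Of 31 proteasome subunits 5 fell (4 adjusted over the list alone), with a median of -0.54, and of 28 neuroblast and neurogenic genes 7 fell (9 adjusted over the list alone), with nerfin-1 foremost. These 3 lists passed camera (adjusted p = 1.3e-10, 2.1e-06 and 6.3e-05) but not when the correlation was estimated (adjusted p = 0.503, 0.503 and 0.588 with an estimated correlation). Falls were also found in 6 of 22 mesoderm and myoblast genes, with 1 rise (6 and 1 adjusted over the list alone), in 4 of 19 pair-rule and segment polarity genes (2 adjusted over the list alone) and in 1 of 13 tracheal genes (1 adjusted over the list alone). That tracheal gene was rib, 6.62-fold lower, whose call was lost with the day as a random block and without the array of 7h20m - 9h20m or 9h20m - 11h20m. Camera gave these 3 lists adjusted p = 0.0011, 0.0045 and 0.0151, and none passed when the correlation was estimated (adjusted p = 0.503, 0.588 and 0.503 with an estimated correlation).

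**Figure D3:**
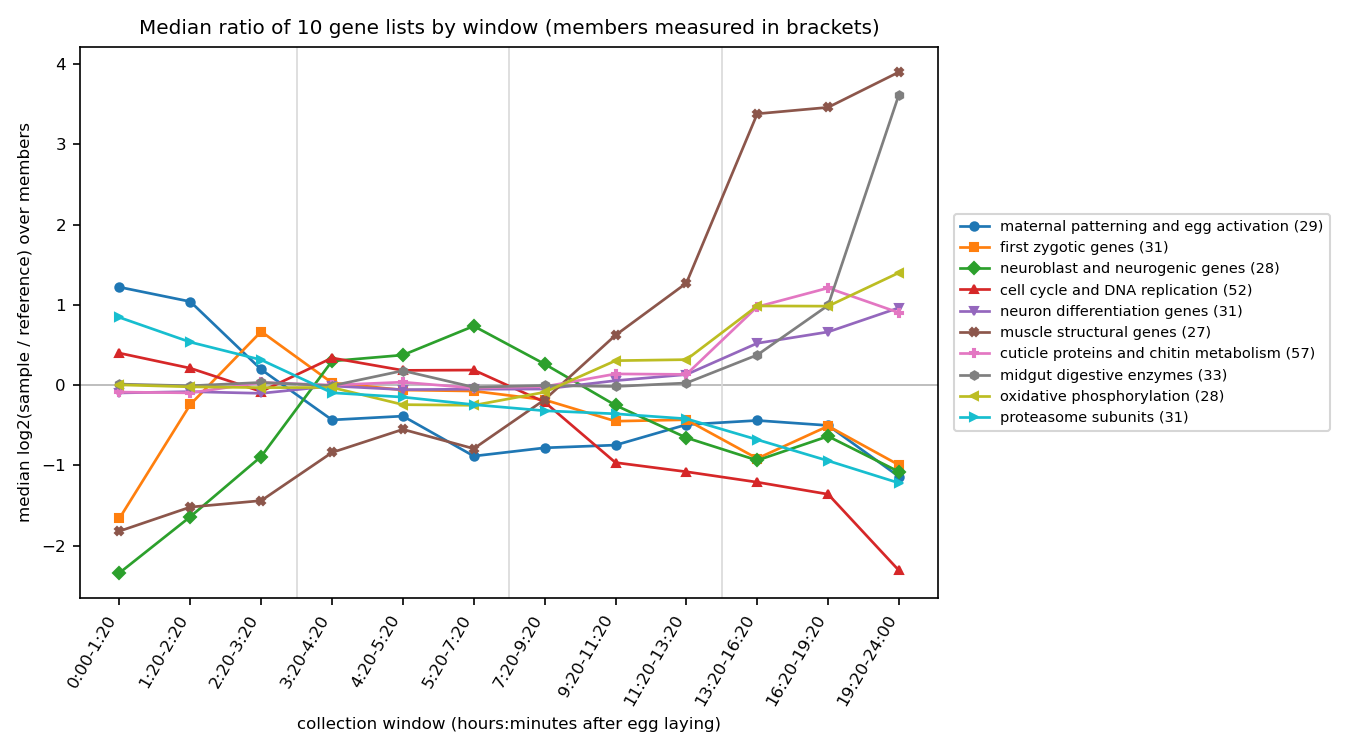
Median log2 ratio of Cy3 sample to Cy5 reference over the members of 10 gene lists (y axis) against window number (x axis), 1 array per point and no error bar because no window has a replicate. Cell cycle and DNA replication genes go from 0.40 in window 0 to -2.31 in window 11, muscle structural genes from -1.82 to 3.90, and midgut digestive enzymes reach 3.62 in window 11.

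In this comparison 2249 genes were higher and 1120 lower (3369 of 12855, 26.2%), 1135 and 310 of them by more than 2-fold. The periods did not overlap in 48.4% of genes (chance 10% for exchangeable arrays). The share of higher calls depended on the scaling: it was 66.8% with loess, 38.8% with median centring, 47.0% with the scanner software's ratios and 43.2% from Cy3 alone. Each of these periods was 1 image extraction day, so day and age cannot be told apart. With the day as a random block 1062 genes passed, and 1777 and 1822 passed without the array of 7h20m - 9h20m or of 9h20m - 11h20m.

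The last comparison, period 4 against period 1, spanned the time course and gave the widest changes. By its brightest probe Act57B rose 374-fold (log2 8.55 ± 0.64, adjusted p = 1.5e-05) and by its other probe 8.42-fold (log2 3.07). Mlc2 rose 357-fold (8.48 ± 0.75), and 12.5-fold by the most different of its 4 probes. Msp300 (CG31916), a giant muscle scaffold of the nesprin family, rose 187-fold, Mlp60A (CG33149), a muscle LIM protein gene, 160-fold, and Nplp2 (CG11051), a neuropeptide-like precursor gene, 118-fold. The most different of the other probes gave a log2 change of 0.24 for Msp300 and -0.027 for Mlp60A. EAChm rose 122-fold and was well above background on 2 of the 3 early arrays. The falls were led by the histone gene His2A:CG31618 (35.6-fold lower, log2 -5.16 ± 0.43, adjusted p = 2.5e-05, and -0.071 by its other probe). Probes of this gene had passed in opposite directions in period 2 against 1. Also among the largest falls were Hsp27 (CG4466), a small heat shock gene (21.2-fold lower), and yl (20.2-fold lower). osk was 15.6-fold lower (-3.97 ± 0.63), me31B (CG4916), a helicase of stored mRNA, 14.7-fold lower, and wisp (CG15737), the poly(A) polymerase of egg activation, 14.4-fold lower. Each of these calls held under every alternative tried.

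Muscle structural genes rose in 25 of 27 cases (25 adjusted over the list alone), with a median of 5.18. Cuticle and chitin genes rose in 46 of 57 cases and 1 fell (47 and 2 adjusted over the list alone), with a median of 1.39, verm by 78.8-fold (11.4-fold by its other probe) and Lcp65Ag1 by 71-fold. Oxidative phosphorylation genes rose in 27 of 28 cases (27 adjusted over the list alone), with a median of 1.15, SdhC by 4.37-fold and ox (CG8764), a subunit of the cytochrome bc1 complex, by 3.4-fold. Neuron differentiation genes rose in 26 of 31 cases and 1 fell (26 and 1 adjusted over the list alone), with nrv3 45-fold and fne 14.1-fold higher. Hemocyte and basement membrane genes rose in 17 of 25 cases (18, with 1 fall, adjusted over the list alone), with Glt 102-fold and Ppn (CG33103), papilin, 86.7-fold higher (13.5-fold by its other probe). Fat body and hemolymph genes rose in 8 of 13 cases (8 adjusted over the list alone), apolpp by 79.6-fold and Apoltp (CG15828), its lipid transfer partner, by 31.6-fold. Midgut digestive enzymes rose in 16 of 33 cases (16 adjusted over the list alone). All 7 lists passed camera, with adjusted p between 7.9e-10 for muscle and 0.0059 for fat body. None passed when the correlation was estimated (adjusted p = 0.293 with an estimated correlation for 6 of them and 0.605 for midgut).

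Of 52 cell cycle and DNA replication genes 51 fell and 1 rose (51 and 1 adjusted over the list alone), with a median of -1.90, CycA (CG5940) 11.9-fold lower and CycE (CG3938) 9.99-fold lower (log2 -0.88 by its most different other probe). Proteasome subunits fell in 22 of 31 cases and none rose (23 fell adjusted over the list alone), with a median of -1.42, Prosalpha1 6.74-fold lower and Prosalpha4 (CG3422) 5.8-fold lower. Maternal patterning and egg activation genes fell in 24 of 29 cases and 1 rose (25 and 1 adjusted over the list alone), and germ plasm and posterior mRNAs in 9 of 17 (9 adjusted over the list alone). Camera gave these 4 lists adjusted p = 2.8e-16, 1.9e-10, 1.8e-08 and 7.7e-04, and none passed when the correlation was estimated (adjusted p = 0.293, 0.293, 0.3 and 0.413 with an estimated correlation). Of 31 first zygotic genes 5 rose and 8 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.185), with the cellularisation gene slam (CG9506) 12.9-fold lower. Of 46 large-subunit ribosomal protein genes 21 rose and none fell (21 adjusted over the list alone), with a median of 0.21. The list passed camera (adjusted p = 0.0099) but not from Cy3 alone or with median centring, nor when the correlation was estimated (adjusted p = 0.544 with an estimated correlation). Of 33 small-subunit ribosomal protein genes 10 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.588), with a median of 0.099 that became -0.021 from Cy3 alone and -0.048 with median centring.

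Between the ends of the course 3994 genes were higher and 2417 lower (6411 of 12855), 2293 and 1111 of them by more than 2-fold. The periods did not overlap in 55.1% of genes (chance 10% for exchangeable arrays). The share of higher calls was 62.3%, against 46.6% with median centring, 47.1% with the scanner software's ratios and 46.8% from Cy3 alone. The median change of all genes moved from 0.072 to -0.085 and -0.045 under the last 2, so small rises stand against that shift. In 267 genes 2 probes of the gene were called in opposite directions, against 78, 0 and 24 genes in the first, the second and the third comparison, out of 6640 genes with more than 1 tested probe.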

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

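The fits with image extraction day as a random block were chosen after the results were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each window has only replicate 1. A count is called unchanged here when it stayed within 1.5 times its reported value. The total count for period 4 against 1 was unchanged under every alternative tried, from 4752 with the day as a random block to 6927 with median centring. The genes behind the total changed more. With median centring 4563 of the 6411 calls recurred in the same direction and 68 were called in the opposite one. Lower calls went from 2417 to 3698 and higher calls from 3994 to 3229. The order of the arrays kept a Spearman rho of at least 0.993, and Cy3 spread more than Cy5 in 94.3% of genes when each channel was normalised by itself.

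With image extraction day as a fixed block, 521 genes passed for period 2 against 1 and 1749 for the stage trend. With the day as a random block, 1266 passed for period 2 against 1, 0 for period 3 against 2 (1324 at an unadjusted p under 0.05 by limma) and 1062 for period 4 against 3. A fixed block leaves to the periods only what differs within a day, so lower counts follow from its construction. The random block sets the periods against a spread between days, which was estimated only from window 2 against windows 0 and 1. That spread holds development too, so the counts with a random block do not separate day from age. For period 3 against 2 the count was 152 without background subtraction, 495 with the scanner software's log ratio, 495 with the deposited value table and 201 from Cy3 alone; the cause was not tested. A straight line in place of the spline passed 5664 genes, since it has no term for genes that peak or dip in the middle of the course. The stage trend was otherwise unchanged, from 8507 with Cy3 alone to 10109 with a trended and robust prior.

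Leaving out each array in turn gave 947 (without 5h20m - 7h20m) to 3470 genes (without 2h20m - 3h20m) for period 2 against 1. It gave 0 (without 1h20m - 2h20m and 4 other arrays) to 1258 (without 7h20m - 9h20m) for period 3 against 2, and 1777 (without 7h20m - 9h20m) to 4251 (without 2h20m - 3h20m) for period 4 against 3. A left-out array takes a residual degree of freedom, but counts also rose, and the cause was not tested. An array outside both periods enters only through the shared spread.

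Camera with an estimated correlation passed 0 lists where the preset correlation passed 56, with 0 in period 2 against 1 (6 lists at an unadjusted p under 0.05), 0 in 3 against 2 (1 list), 0 in 4 against 3 (2 lists) and 0 in 4 against 1 (4 lists). With the scanner software's ratios 52 passed, from Cy3 alone 59 and with median centring 64. The larger correlation widens the error of a list by construction.

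Of 9528 values of named genes under the alternatives, 8329 stayed on the same side of the threshold. A further 1099 kept their direction and no longer passed, 86 kept it and newly passed, and 14 that passed in either fit reversed. Values that passed in neither fit count among the 8329 whatever their direction. The scanner software's ratios and the deposited value table hold the same values and were both counted. With the mean of all probes the log2 change of bnk became -1.42 and that of Csp -0.0030 in period 2 against 1, and those of bnk and repo became -0.79 and 0.81 in period 4 against 1, because these probes of 1 gene differ in course. With median centring eIF1A became -0.16, Obp83a -0.16, Cp38 0.089, Orco -0.0038 and RpS26 -0.048 in period 4 against 1, and Tsf1 became -0.076, dec -0.14, bam -0.24, Or94b -0.029 and Orco -0.065 in period 4 against 3; the cause was not tested. Dim signal limits what can be read in 304 probes that were never well above background in Cy3. Omitting the filter on dim probes gave 2012, 261, 3375 and 6427 genes in the 4 comparisons, against 2029, 312, 3369 and 6411.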

Other observations

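The tests without the array of 16h20m - 19h20m, of the step between periods 2 and 3, and of late-embryo RNA in the reference were chosen after the results were seen. Several gene lists had smaller or later changes than those described above. Of 15 salivary gland genes 6 rose in period 2 against 1 (7 adjusted over the list alone), with a median of 0.25, including the RNA-binding gene ps (CG16765; 7.45-fold, log2 2.90 ± 0.33) and CrebA (CG7450; 3.48-fold), a transcription factor of secretory cells. The list passed camera (adjusted p = 0.0052) but not when the correlation was estimated (adjusted p = 0.243 with an estimated correlation). In period 3 against 2, 2 members rose (4 adjusted over the list alone), with a median of -0.04, a mean of 0.34 and an upward camera direction (adjusted p = 0.252). Later, in period 4 against 3, 4 members fell, CrebA among them (2.13-fold lower), and 1 rose (4 and 2 adjusted over the list alone), with a median of -0.098 that became 0.096 with median centring (camera adjusted p = 0.209). In period 4 against 1, 8 rose and 1 fell (8 and 1 adjusted over the list alone), and ps was 24-fold higher (1.44-fold by its most different other probe). Of 25 ecdysone synthesis and response genes 2 rose in period 2 against 1 (2 adjusted over the list alone), led by ImpL2 (CG15009; 15.4-fold), and 1 fell in period 3 against 2 (1 adjusted over the list alone). Of the ecdysone genes 3 rose in period 4 against 3 (1 adjusted over the list alone). In period 4 against 1, 5 rose and 2 fell (5 and 0 adjusted over the list alone), with Cyp18a1 (CG6816), which inactivates ecdysone, 9.68-fold and the response genes Eip74EF (CG32180) and Eip75B (CG8127) 4.51-fold and 2.67-fold higher (log2 changes of -0.091 and -0.16 by their most different other probes). The list passed camera in no comparison (adjusted p of 0.713, 0.401, 0.251 and 0.994 in order), and its last median of 0.14 became -0.139 with the scanner software's ratios and -0.119 from Cy3 alone.

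Of 22 immune effector genes 0 passed in the first and second comparisons, 4 rose in period 4 against 3 (3 adjusted over the list alone) and 7 in period 4 against 1 (7 adjusted over the list alone). They included the peptidoglycan amidase gene PGRP-LB (CG14704; 8.06-fold and 7.86-fold, with log2 changes of -0.048 and -0.10 by its most different other probe), the lysozyme gene LysB (CG1179; 2.53-fold and 3.65-fold) and Drs (CG10810), the antifungal peptide drosomycin (2.76-fold in the last). Camera did not pass the list in any comparison (adjusted p of 0.867, 0.517, 0.152 and 0.206), but did in period 4 against 3 with the scanner software's ratios, Cy3 alone and median centring (adjusted p = 0.0319, 0.0233 and 0.0020). Of 28 sensory receptor genes 7 rose in period 4 against 3 (7 adjusted over the list alone). That list passed camera (adjusted p = 0.0106; adjusted p = 0.588 with an estimated correlation). In period 4 against 1, 10 rose (8 adjusted over the list alone; camera adjusted p = 0.273), with a median of 0.12 that became -0.052 with the scanner software's ratios, and nompA (CG13207), which links sense organ dendrites to their cuticle, was 2.42-fold higher. Of 13 heat shock genes 5 rose and 1 fell in period 2 against 1 (6 and 2 adjusted over the list alone), with a median of 0.81 and a mean of 0.094 (camera adjusted p = 0.156). Hsp67Bc (CG4190) rose 8.41-fold in period 3 against 2, a call that 7 of the arrays left out in turn ended. Falls were found in 2 heat shock genes in period 4 against 3 (1 adjusted over the list alone; camera adjusted p = 0.012, but adjusted p = 0.503 with an estimated correlation). Over the whole course, in period 4 against 1, 2 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.528). Of 19 follicle cell, chorion and yolk genes 2 fell in period 2 against 1 (2 adjusted over the list alone), with a median of 0.001 and a mean of -0.46, 1 rose and 1 fell in period 4 against 3 (0 and 0 adjusted over the list alone), and 4 rose and 5 fell in period 4 against 1 (4 and 5 adjusted over the list alone), with a median of -0.069 that became 0.095 with median centring. In the last comparison fs(1)N (CG11411), an eggshell gene, was 6.66-fold lower, a call lost without the array of 1h20m - 2h20m. Of 16 germ cell and testis genes 3 fell and 1 rose in period 2 against 1 (3 and 1 adjusted over the list alone), 1 fell and 2 rose in period 4 against 3 (1 and 1 adjusted over the list alone), and 6 fell and 1 rose in period 4 against 1 (6 and 1 adjusted over the list alone; the median of -0.059 became 0.045 with median centring), with otu (CG12743) 5.31-fold and piwi (CG6122) 2.53-fold lower. Of 16 adult tissue genes 0 passed in the first and second comparisons, 2 rose and 1 fell in period 4 against 3 (2 and 1 adjusted over the list alone), and 4 rose and 3 fell in period 4 against 1 (4 and 3 adjusted over the list alone), with a median of 0.14, a downward camera direction and TpnC41C (CG2981), a muscle troponin C, 2.99-fold higher; the median became -0.085 with the scanner software's ratios. The 11 genes that serve as controls of RNA quality were not constant. Gapdh1 (CG12055) was 10.3-fold lower in period 2 against 1, a call lost with image extraction day as a block, and alphaTub84B (CG1913) was 2.37-fold lower in period 4 against 3. In period 4 against 1, 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of 0.20 that became -0.151 from Cy3 alone and -0.164 with median centring. Camera passed the follicle, germ cell, adult tissue and RNA quality lists in no comparison (adjusted p of at least 0.0918).

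Of the 1214 genes that rose in period 2 against 1, 248 fell in period 4 against 3, where independent lists would share 105.8, and 112 rose again, against 212.4. The comparisons have no array in common but share the estimate of the spread, and the difference from independent lists was not tested. Other orders and splits of the arrays were fitted as well. Of 100 orders of the 12 arrays 1, the real one, passed 9736 genes in the stage trend and the highest other passed 2672. None of the other drawn orders thus reached the real count. A drift with image extraction day, which follows the windows, may also set the real order apart from shuffled ones. The test therefore does not tell day from age. For each of the 4 comparisons the 6 arrays make 10 splits, too few for a share under 0.05, and 1 split, the real one, reached its count. The real and highest other counts were 2029 and 1, 312 and 0, 3369 and 26, and 6411 and 2.

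The genes called between periods 3 and 4 coincide with a change of image extraction day. The Cy5 reference alone, the same RNA on every array, gave 22 calls against 3369 (2162 at an unadjusted p under 0.05 by limma). Few of the calls thus went with a called change in the reference. Between periods 1 and 4 the reference differed in 208 genes (4437 at an unadjusted p under 0.05). A shift shared equally by both channels cancels in the ratio, and a shift of Cy3 alone leaves Cy5 unchanged. The reference therefore cannot decide whether the day gave rise to the calls. Without the array of 16h20m - 19h20m 2430 genes passed, so that array is not the whole source. The 3 steps that cross a day had a root mean square of 0.589 (windows 1 to 2), 0.253 (5 to 6) and 0.634 (8 to 9), against a median step within a day of 0.373, so the middle one argues only against a difference of like size at every change of day, and a day effect at the other crossings is not excluded. Cy3 labelling or RNA preparation that differed between these days cannot be separated from age and stays open beside development, which the design names.

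In 267 genes 2 probes of the gene were called in opposite directions between periods 1 and 4. In 1.12% of them an opposed probe was above background on fewer than 6 arrays. Kept probes had to be so on at least 3 arrays, and most probes were so on every array. No share was taken for other genes, so the value does not decide on dim probes. Low-complexity sequence was found in 9.52% of the opposed probes against 7.6% of probes of genes called one way, a difference too small to decide. The permutation test (p = 0.00065) was of another measure, the share of genes with any such called probe. It did not match genes on their number of called probes, so it does not decide either. Of the genes with opposed probes 70.8% had 3 or more RefSeq transcripts, against 60.9% in genes with as many probes called one way (permutation p = 2e-04, 260 and 2592 genes). Alternative transcripts that switch with age may therefore account for part of the genes with opposed probes. That is a hypothesis, and the probes were not placed on transcripts.

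On the array of 16h20m - 19h20m the Cy5 reference departed from its level on the other arrays by more than 2-fold in 453 genes, 446 of them higher, against 107 on the array of 19h20m - 24h00m and at most 26 on any other. The largest departures were Lcp65Ag2 (log2 3.43), Lcp65Ag3 (3.26) and TwdlB (3.24), all cuticle genes and chosen after their values were seen, and 13 of 57 cuticle genes departed so far. Departures of adjacent spots correlated at r = 0.056 across spots, which argues against a local artefact on this slide. On the other arrays this r lay between 0.0443 and 0.446. It was highest on the arrays of 4h20m - 5h20m (0.341) and 5h20m - 7h20m (0.446), where a local artefact in Cy5 is not excluded. The same measure of the log2 ratio was 0.0103 and 0.00626 on those arrays. Of the departing genes 2.87% lay among the dimmest ones. The offset added in background correction shrinks the departures of dim spots, and the departing genes were chosen for departures over 2-fold. Their low share among the dimmest ones therefore does not decide on low signal. The Cy5 and Cy3 departures of these genes correlated at r = 0.683 across genes, which are not independent replicates, as a spot or hybridisation effect shared by both dyes may give, though genes active late give it too. The Cy5 departure also correlated with the mean ratio of both neighbouring windows at r = 0.488, against 0.292 over all genes, and the source of the signal stays undecided.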
